A study of Sinorhizobium meliloti with 4 samples.

How the data were processed

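RNA was sequenced from 4 cultures of the nitrogen-fixing soil bacterium Sinorhizobium meliloti. According to the labels, 2 biological replicates were grown on methanol with lanthanides (MeOH + Ln) and 2 carry the label Gly + Ln. Per the labels' protocols, a wild-type strain grew in 50 ml of minimal medium. The protocols name methanol at 0.5%, glycerol at 0.1% and lanthanides at 30 μM, and can be read as methanol plus glycerol for one of the media, so it stays open whether the Gly + Ln cultures also received methanol. Cells were harvested at an optical density between 0.4 and 0.9. Ribosomal RNA was depleted before random-primed cDNA synthesis.

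The authors deposited a table of raw counts per feature and a table of TPM values (library-scaled and length-scaled counts), both with 6333 features and 1 column per library. Per the submitters' processing notes, Trimmomatic 0.36, Bowtie2 2.2.6, featureCounts of Subread 1.5.2 and DESeq2 were used. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of overlapping features on opposite strands cannot be told apart. The deposited counts are whole numbers. Each column of deposited TPM values has the same sum, and count divided by TPM gave 1 relative length per feature in all libraries. At a median of 870 bases for features with over 20 counts in every library, these lengths were whole numbers (within 0.05 bases) for 100% of the 2763 features with over 500 counts in every library. Among the 6332 features with a length, 97.1% had a length divisible by 3. Some rows have lengths of the size of transfer or ribosomal RNA, so lengths are given in bases and are not taken as coding lengths.

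The features carry locus tags, and the deposited tables do not pair them with gene names. The gene table used here (assembly ASM3006458v1, another strain) matched 0 of the 6333 identifiers. The 25 gene lists fixed beforehand, the comparison between replicons and the account of xoxF therefore could not be computed. Ribosomal RNA rows were to be left out, but no row is named as such, and the main fit kept all rows. By length alone, 3 blocks of 6 rows with the same lengths in the same or reverse order (1485, 77, 76, 2859, 115 and 77 bases) are candidates for ribosomal RNA operons. These 18 rows took 2.99% and 2.77% of counts in MeOH + Ln and 1.02% and 2.86% in Gly + Ln, and the main fit called 0 of them while DESeq2 called 1. Features are described by their level, their length and their position in the table, and the identifiers printed are the first 2 of each direction under the rule for named genes. That rule took the 10 called features with the largest rise and the 10 with the largest fall, at a mean CPM (counts scaled to the library total) of at least 10 and with both MeOH + Ln values on one side of both Gly + Ln values. Neighbouring rows of the table carried identifiers 5 apart in 5567 of 6332 steps. The authors' files do not state that the rows follow the genome. A run means consecutive rows that all passed the test in one direction. Runs and neighbours were examined after the values had been seen.

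Total counts were 17661935 and 18668325 for MeOH + Ln replicates 1 and 2, and 18851315 and 15427792 for Gly + Ln replicates 1 and 2. Features with fewer than 10 counts numbered 91 and 120 in the MeOH + Ln libraries and 49 and 72 in the Gly + Ln libraries.

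The counts were compared with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter (6290 features kept), robust quasi-likelihood fits with the group as the only term, and two-sided F tests. P-values were adjusted by the Benjamini-Hochberg method and a feature was called at an adjusted p under 0.05. Positive log2 fold changes mean higher in MeOH + Ln. Standard errors (SE) of log2 fold changes were computed as the fold change divided by the square root of F. CPM values are TMM-normalised. With 2 libraries per group, 2 residual degrees of freedom remained. The common dispersion of 0.0686 corresponds to a biological coefficient of variation of 26.2%. On simulated data with 200 changed features, the test on this comparison (6270 features) recovered 16% of features with a true log2 change of 1, 94.7% at 2 and 100% at 4, and called 9 of 6071 unchanged features. Changes near 2-fold were thus mostly missed in the simulation. It changed 200 features, fewer than the 734 called in the data, so its adjusted threshold was stricter. The 16% may therefore understate the share recovered in the data. The simulated features were drawn independently with the dispersions estimated here. The simulation therefore does not cover neighbours that change together or the choice of scaling.

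Alternatives fixed before the data were examined were DESeq2 size factors, total counts only and upper quartile scaling within edgeR, DESeq2 1.42.0 and limma-voom (limma 3.58.1) as tools, no filter on low counts and a mean count of at least 50, limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 1, the replicate number as a block, and each library left out in turn. Leaving out near-equal copies, leaving out the 3 blocks of candidate ribosomal RNA rows, and leaving the 100 most counted features out of both totals and test without TMM were added after the data had been seen. Near-equal copies are features of one length with a mean of at least 1000 counts whose counts differ by less than 0.05 on the log2 scale in every library, and 3 pairs met this. Calls were shuffled over the tested rows 10000 times to test their order. Further steps used Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1.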

Results

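The data comprised 4 RNA-seq libraries of Sinorhizobium meliloti, 2 from cultures on methanol with lanthanides (MeOH + Ln) and 2 labelled Gly + Ln. The series is about XoxF, a methanol dehydrogenase that needs a lanthanide, and its design text speaks of growth with and without lanthanides. All 4 libraries analysed here carry the lanthanide label, so the comparison they allow is between the growth media, with lanthanides in both. Libraries held between 15427792 and 18851315 counts over 6333 features. Pearson's r of log2 CPM across features, which are not independent replicates, was 0.966 between the MeOH + Ln replicates and 0.974 between the Gly + Ln replicates. Between the groups it ranged from 0.909 to 0.924. The labels call the replicates biological without saying what was separate, so p-values measure the spread between these libraries. The files pair none of the features with a gene name, and levels of xoxF are not reported.

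Growth on methanol with lanthanides went with a strong rise of a small set of features. Of 6290 features tested, 354 rose and 380 fell in MeOH + Ln relative to Gly + Ln (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 11.7% of those tested. The median change was 3.01-fold among risers and 2.77-fold among fallers. At least 2-fold changes were seen for 318 risers and 352 fallers, at least 4-fold for 122 and 90, and at least 16-fold for 25 and 12. At least 64-fold changes were seen for 10 risers and 0 fallers. Risers had a median of 174 CPM in MeOH + Ln and 49.9 CPM in Gly + Ln, and fallers had medians of 25.6 and 78.8 CPM. Features not called had medians of 29.8 and 31.1 CPM. Each called group is high by selection in the medium where it was called higher. Risers made up 23.0% and 22.5% of all counts in the MeOH + Ln replicates and 5.71% and 5.66% in the Gly + Ln replicates. Fallers made up 1.72% and 1.83% in MeOH + Ln and 10.3% and 9.11% in Gly + Ln. Of the risers, 33 lay below 10 CPM in both Gly + Ln libraries and above it in both MeOH + Ln libraries, and 49 fallers showed the mirror image. Values of the groups did not overlap for 58.8% of the tested features. For a single feature, exchangeable libraries give 33.3% for 2 against 2. Features of one library are not independent, so the share was not tested against that value.

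**Figure D1:**
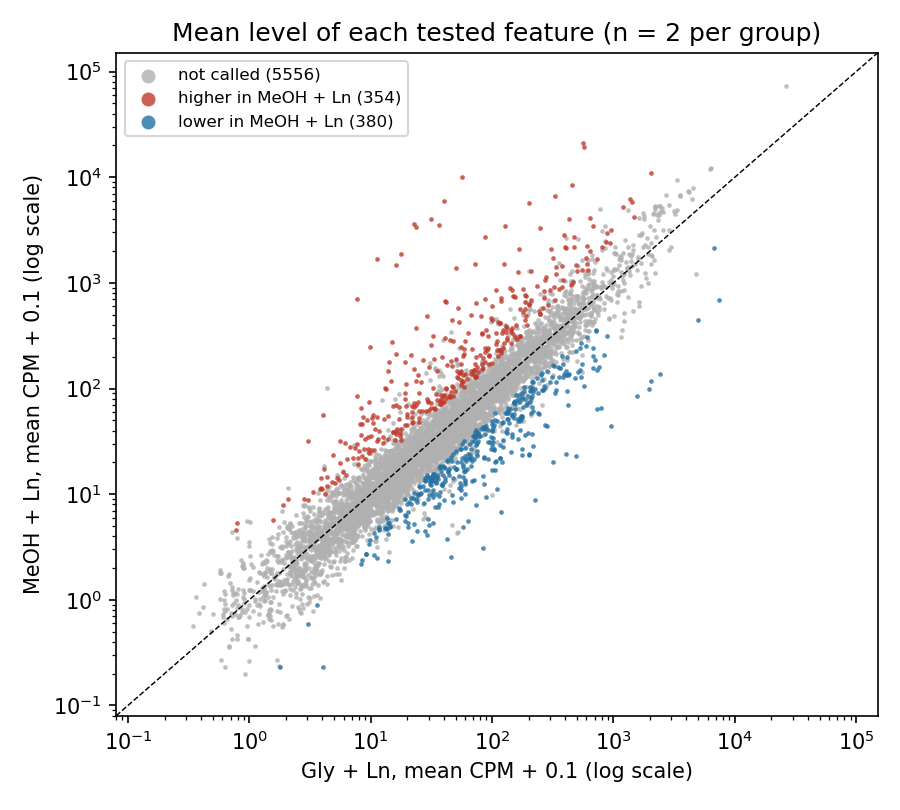
Mean CPM of each of the 6290 tested features in Gly + Ln (horizontal axis) and MeOH + Ln (vertical axis), with 0.1 added and both axes on a log scale. Each point is a feature, red for the 354 that rose, blue for the 380 that fell and grey for the 5556 not called, and the risers reach farther from the dashed line of equality than the fallers.

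These counts depended on the scaling and on single libraries. With total counts as the only scaling, the median log2 change of all features moved to -0.57, and 208 features rose while 1501 fell (12.2% risers among the calls, against 48.2% with TMM). With TMM the median was -0.029, and all changes are given relative to it. DESeq2, which the submitters list, called 599 risers and 548 fallers. Without Gly + Ln replicate 1 the calls numbered 176, and without Gly + Ln replicate 2 they numbered 311, the single remaining library being assumed to vary like the other group.

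The largest rise was that of SM2011_RS07535, a feature of 1461 bases, from 56.6 ± 4.10 CPM in Gly + Ln to 10010 ± 1176 CPM in MeOH + Ln (SD, n = 2). Its log2 fold change was 7.47 ± 0.51 (SE), or 177-fold, with an edgeR adjusted p of 0.000201. SM2011_RS07530, the row before it, with 390 bases, rose 157-fold from 22.8 ± 2.06 to 3576 ± 554 CPM (SD, n = 2; edgeR adjusted p = 0.000191). The 10 largest risers ranged from 92.2-fold to 177-fold. The largest fall was that of SM2011_RS00780 (789 bases), from 84.0 ± 1.12 CPM in Gly + Ln to 2.96 ± 1.02 CPM in MeOH + Ln, with a log2 fold change of -4.82 ± 0.32 (SE; edgeR adjusted p = 0.000192). SM2011_RS26230 (282 bases) had 225 ± 20.9 CPM in Gly + Ln and 8.69 ± 0.31 CPM in MeOH + Ln, a log2 fold change of -4.69 ± 0.25 (SE; edgeR adjusted p = 0.000189). The 10 largest fallers ranged from 17.2-fold to 28.2-fold lower. All 4 features kept their direction and their call in every alternative that tested them.

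**Figure D2:**
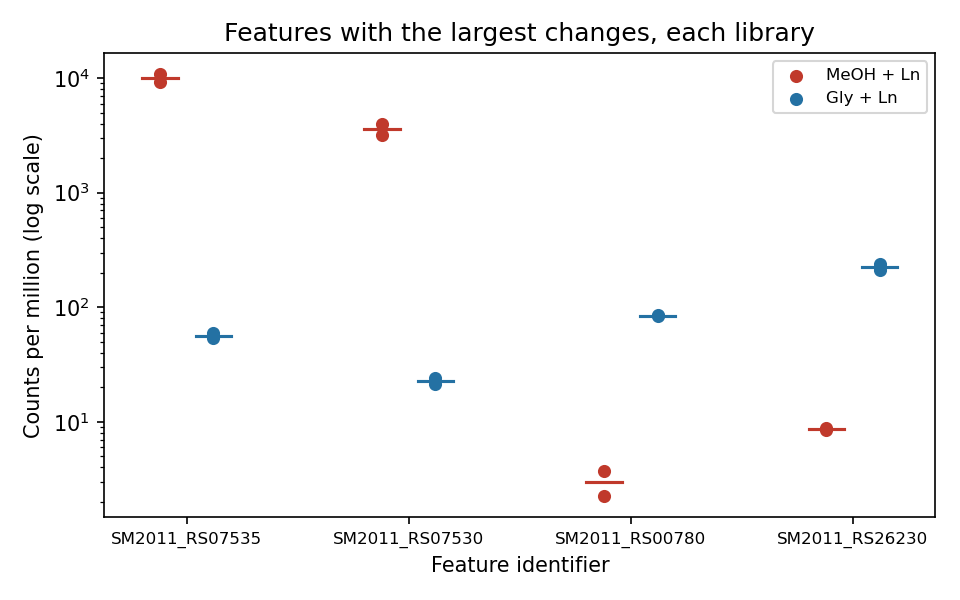
CPM (log scale) of the 2 largest risers and the 2 largest fallers. Dots are single libraries and short lines are group means, and for each feature the 2 MeOH + Ln dots (red) lie apart from the 2 Gly + Ln dots (blue).

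The strongest risers stood side by side in the table. Rows 4950 to 4987, which hold SM2011_RS07530 and SM2011_RS07535, formed a run of 38 consecutive risers with a median rise of 14.1-fold and a range from 2.2-fold to 177-fold. This run held 9 of the 10 largest risers, and 19 of its members rose at least 16-fold, out of 25 such features among all risers. Its members took 9.28% and 8.04% of all counts in the MeOH + Ln replicates, and 0.409% and 0.356% in the Gly + Ln replicates. In the deposited TPM values the run made up 15.6% and 15.2% of the total in MeOH + Ln and 0.743% and 0.749% in Gly + Ln. Most of that came from 1 short member of 96 bases, the feature with the highest TPM in both MeOH + Ln libraries, at 103238 and 108111 TPM. In Gly + Ln the same feature had 4630 and 5188 TPM, a log2 fold change of 5.06 ± 0.52 (SE; edgeR adjusted p = 0.00114). The TPM of so short a feature depends strongly on its assigned length. With total counts only, 35 of the 38 members still rose, but the longest run held 18 risers. With the replicate number as a block 37 did, and the longest run held 19. Leaving out either Gly + Ln library also shortened the longest run.

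**Figure D3:**
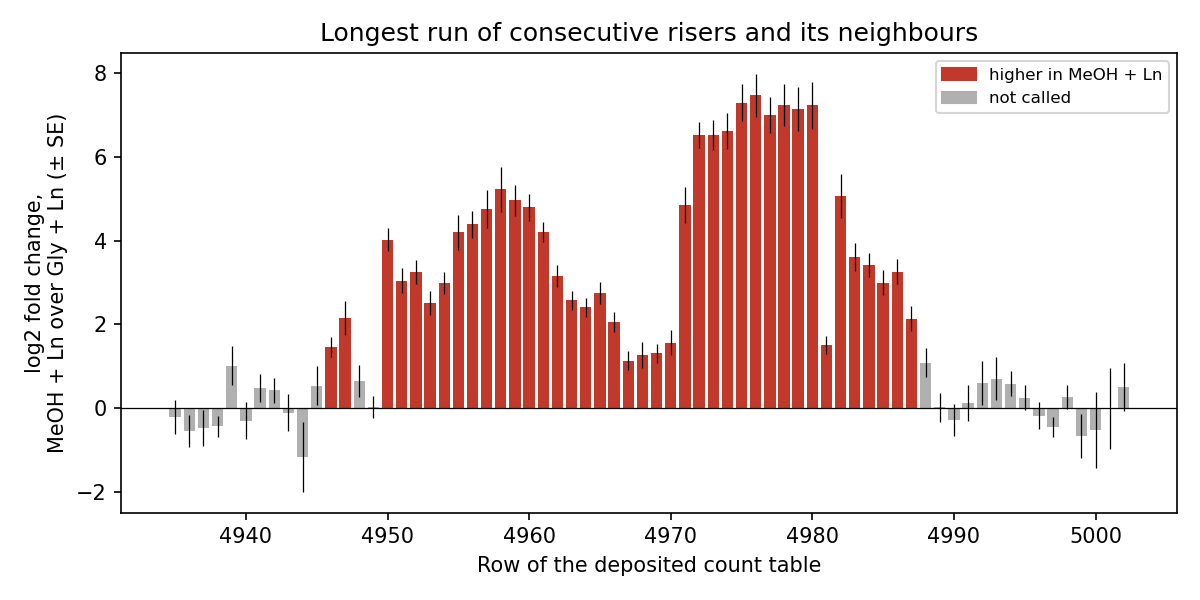
Log2 fold change of MeOH + Ln over Gly + Ln for each tested feature around rows 4950 to 4987 of the deposited count table, with error bars of ± 1 SE. Red bars passed the test and grey bars did not, and the changes form 2 peaks within the run, the higher one reaching 7.47.

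How the longest runs of risers and fallers compared depended on the scaling. With total counts only, and with the deposited TPM values, the longest held 18 risers and 17 fallers. With TMM the longest faller run, rows 3109 to 3117, held 9 consecutive fallers with a median fall of 17.8-fold and 6 of the 10 largest fallers. These 9 features took 1.42% and 2.49% of all counts in the Gly + Ln replicates and 0.104% and 0.097% in the MeOH + Ln replicates. A run of 6 risers, rows 3101 to 3106, lay 2 rows away, with a median rise of 14.5-fold. The riser run took 0.872% and 0.766% of counts in MeOH + Ln and 0.0744% and 0.0641% in Gly + Ln. All 9 features of the faller run were called without each of the 4 libraries in turn.

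The most abundant feature by counts did not pass the test. This feature, of 1038 bases, took 6.82% and 5.44% of all counts in the MeOH + Ln replicates. It took 1.27% and 4.84% in the Gly + Ln replicates, so that its level in Gly + Ln replicate 1 lay apart from that in the other 3 libraries. Its log2 fold change was 1.46 ± 0.77 (SE), with an edgeR adjusted p of 0.265. The 10 most counted features of each library took 15.5% and 16.2% of its counts in MeOH + Ln and 6.86% and 11.5% in Gly + Ln.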

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

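The choice of scaling and leaving out either Gly + Ln library moved the counts most, and no alternative reversed a called feature among the 734. With total counts only, 1709 features were called (208 higher and 1501 lower in MeOH + Ln), of which 1452 changed at least 2-fold (191 and 1261). The deposited TPM values, which have no further scaling between libraries, gave 2033 calls (179 and 1854), 1661 of them at least 2-fold (164 and 1497), on log2(TPM + 1), and 2001 (178 and 1823), 1730 of them at least 2-fold (167 and 1563), on log2(TPM + 0.1). Leaving the 100 most counted features out of both the totals and the test, with no TMM, changed the scaling and the features tested together. It tested 6179 features and gave 252 risers and 665 fallers, of which 236 and 577 changed at least 2-fold. Of the 734 calls, 25 were not tested there, and 29 of the 38 members of the longest run were called risers, 8 of the 38 having been left out. DESeq2 called 1147 features, 599 of them higher, and kept 733 of the 734 calls. Leaving out each library in turn gave 176 to 978 calls (85 to 476 higher, 91 to 536 lower) and 176 to 959 calls of at least 2-fold (85 to 465 higher, 91 to 536 lower). The lowest values came without Gly + Ln replicate 1. Without Gly + Ln replicate 2, 311 features were called and 260 of the 734 calls were kept. Both fits took the spread from the MeOH + Ln pair alone, whose effect was not tested.

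The longest runs held 38 risers and 9 fallers in the main fit, 18 and 17 with total counts only and on both TPM scales, 19 and 9 with the replicate block, and 12 and 7 without the 100 most counted features. Leaving out each library in turn gave 13 to 39 risers and 9 fallers. The share of called features in runs of at least 5 was higher for risers than for fallers in every alternative.

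The replicate numbers were not shown to pair the libraries: deviations of replicates 1 and 2 from their group means had a correlation of 0.0598 between the groups. With the replicate block, 591 features were called. DESeq2 size factors (741 calls), upper quartile scaling (757), limma-voom (663), no low-count filter (728), a mean count of at least 50 (720) and near-equal copies left out (736) stayed within 1.5 times the count of 734. The alternatives for gene lists, replicons and xoxF gave no value because the identifiers are not paired with names, and the fits keep ribosomal RNA rows in the totals because no row is named as such. Leaving out the 3 blocks of 6 rows that are candidates by length gave 742 calls (361 higher and 381 lower), and all 38 members of the longest run were still called. Low counts left out 43 features, and the 2 libraries per group limit calls near 2-fold.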

Other observations

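All tests in this part were chosen after the counts of changed features and the largest changes had been seen. Beyond the longest run, risers gathered in several other stretches of the table. Rows 4057 to 4131 held 4 runs of at least 5 risers, and 40 of the 75 rows there rose while 1 fell. This stretch took 4.67% and 6.63% of counts in the MeOH + Ln replicates and 1.81% and 1.93% in the Gly + Ln replicates. Over the whole table, 10 runs of at least 5 risers held 98 features (27.7% of the risers), and 2 runs of at least 5 fallers held 15 features (3.95% of the fallers). The contrast between risers and fallers was not tested, and these numbers depend on the scaling, the tool and single libraries. With total counts only, 10 runs held 90 risers (43.3% of them) and 35 runs held 215 fallers (14.3%), and DESeq2 gave 19 runs with 183 risers and 6 runs with 35 fallers. Leaving out each library in turn gave 4 to 15 runs with 33 to 173 risers and 1 to 6 runs with 9 to 39 fallers.

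Changed features lay next to each other far more often than a random order gives. Adjacent rows both rose 151 times, against 7 to 38 times in 10000 shuffles of the calls over the tested rows (one-sided permutation p = 0.0001, the smallest the shuffles can give), and both fell 113 times, against 9 to 40. Shared reads between near-equal copies would need such copies in the longest run, and 0 of its 38 members belonged to one. Only 33 members had the 1000 counts needed for the search. It also missed the rows of 1485 and 2859 bases in 1 of the 3 candidate ribosomal RNA blocks, whose counts were unequal to those of the other blocks. The search therefore cannot decide on shared reads between copies with unequal counts. A single library was not the source, since the longest run of risers still held at least 13 features without each library in turn. Neighbours also differed together between the MeOH + Ln replicates. Among the 85 features at least 4-fold higher in replicate 2, 29 adjacent pairs were found. No shuffle was run for these pairs, so adjacency may not be particular to the difference between the media, but this was not tested. A hypothesis left open is that the runs may be groups of genes transcribed together in response to the carbon source. The deposited tables give neither operons nor strands, and differences in growth stage within the harvest range were not tested either.

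The libraries needed unequal scaling, with the median log2 difference of MeOH + Ln minus Gly + Ln at -0.57 on plain totals and between -0.763 and -0.366 in the 4 library pairs. The 100 most counted features, ranked in each library separately, took 43.2% and 44.9% of counts in MeOH + Ln and 26.3% and 34.8% in Gly + Ln. The totals were then taken without 1 common set of 100 features, those with the highest plain CPM summed over the 4 libraries. The shares above are not those of this common set. Without the common set the median was -0.26, and it stayed between -0.347 and -0.164 in the 4 pairs. The common set thus accounts for part of the shift and not all of it. The remainder may come from a broader set of well-expressed features. A difference in total RNA per cell with the same composition would cancel in counts divided by library totals. Neither was measured here.

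The MeOH + Ln replicates differed at least 4-fold in 124 features (with 0.1 added to CPM), against 24 for the Gly + Ln replicates. The SD of the log2 CPM difference was 0.657 in MeOH + Ln and 0.541 in Gly + Ln. The median absolute log2 difference went the other way, at 0.285 and 0.321. Fewer calls without a Gly + Ln library need not mean smaller changes. Without Gly + Ln replicate 1 or 2, SM2011_RS07535 had log2 fold changes of 7.39 and 7.56. Those of SM2011_RS00780 were -4.81 and -4.81. Of the 124, 85 were higher in replicate 2, and those 85 took 8.63% of its counts, 1.33% in MeOH + Ln replicate 1, and 3.65% and 4.91% in the Gly + Ln replicates. Between the groups, edgeR called 0 of the 124, 21 had an unadjusted p under 0.05, and DESeq2 called 21. The 124 were chosen for a large spread within MeOH + Ln, which works against a call. The 0 therefore says nothing further about these features. An exchanged MeOH + Ln and Gly + Ln library was argued against, since the lowest r within a group exceeded the highest r between groups by 0.042. Counting noise of low features stays open for the 32.3% of the 124 with under 50 counts in the higher replicate. The other 67.7% had at least 50 counts there and are not low features in this sense, and 51 of the 85 had at least 500 counts in replicate 2. Poor recovery of short features in one library also stays open. The median length of the 124 was 627 bases, with a 95% bootstrap interval from 468 to 789 bases. That interval includes the 25th percentile of all tested features (492 bases). It pools features higher in replicate 2 with those higher in replicate 1, so it cannot tell whether one library lacked short features. A biological difference between the cultures was not tested.

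The feature that differed most between the MeOH + Ln replicates, of 421 bases, had 2315 and 76861 counts there and 5834 and 9844 counts in the Gly + Ln replicates. The 3 near-equal pairs, with features of 2859, 1485 and 843 bases, took 2.62% and 5.24% of counts in MeOH + Ln and 2.05% and 3.63% in Gly + Ln, and with lengths 3 to 12 bases apart 0 pairs were that close. Their counts are uncertain because reads of near-identical copies can be split between them. The pairs of 2859 and 1485 bases belong to the candidate ribosomal RNA blocks. The features of 843 bases are among the 124 that differed between the MeOH + Ln replicates. They had 47952 and 49155 counts in MeOH + Ln replicate 1, and 308895 and 309628 in replicate 2. Length and log2 fold change had a Spearman correlation of -0.09 across the 6290 tested features, which are not independent replicates (permutation p = 0.0001, the smallest 10000 shuffles can give).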
